A study of Mus musculus with 3 samples.

How the data were processed

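The series holds 3 libraries of RNA from the chromatin fraction of C57BL/6J bone marrow-derived macrophages after 120 min of lipid A at 100 ng/ml, sequenced as ribosomal RNA-depleted total RNA with fragments of 250 to 400 nt, per the labels. The labels number them as biological replicates 1, 2 and 3, which gives a single group, and samples were placed in it from those labels. With 1 group there is no contrast between conditions, so gene lists were placed among all genes of the same libraries, lists and isoforms were contrasted within libraries, and the spread between libraries was measured.

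For each library the authors deposited a gene table and a transcript table of expected counts, which are read totals shared out among features and need not be whole, together with TPM. The column layout of these tables is that of RSEM, and a deposited note says they were made from transcriptome alignments to mm10 with the GENCODE M21 annotation. The authors also deposited a further transcript table of estimated counts and TPM made directly from the reads, whose column layout is that of kallisto, and it is called the other quantifier here. TPM as deposited by the authors divides counts by effective length and scales each library's features to a fixed total. Names and versions of aligner and quantifiers, trimming, duplicates and the strand setting are not given in the sources used here. Without a known strand setting, reads of a gene and of a gene overlapping it on the opposite strand cannot be told apart.

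Symbols, biotypes and coordinates came from the GENCODE M21 reference, which matched 55536 of 81881 entries of the gene table. The unmatched entries are tRNA models and spike-in and control sequences, held 0.845%, 0.282% and 0.179% of all expected counts in replicates 1, 2 and 3, and were left out of library sizes and tests. Where a symbol had more than 1 entry the one with the highest mean TPM was used in lists. All 322 list entries matched a gene. For the other quantifier, transcripts were summed per gene. Nuclear copies of mitochondrial genes were sought among reference transcripts within 5 nt in length that share at least 0.5 of windows of 50 nt, a search added after the data were seen.

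Gene totals were 19751051, 20372850 and 21984526 expected counts. A floor of 3 counts per library was used where a count was 0, and intervals of shares are exact Clopper-Pearson intervals at 95%. Both cover counting error only, since reads are not independent molecules.

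The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. Named genes are the 15 with the highest mean TPM and a length of at least 200 nt, the 3 highest and the 1 lowest measured member of each list, the 8 genes with the largest isoform ratio in each direction among those past the threshold with the same sign in every library and a mean count of at least 100, and the 6 genes with the largest squared coefficient of variation among those past the threshold with a mean count of at least 100. Other genes named below were chosen after their values were seen, which is said where they appear in the closing part, and in the report applies to the list members named with isoform ratios.

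A list's level is the median of log2(TPM + 0.1) over its members, averaged over libraries, and its percentile is taken among 10000 random lists of the same size from all protein-coding genes, or from all annotated genes for nuclear-retained and mitochondrially encoded RNAs. Percentiles outside the central 95% were counted as standing apart, as a description of these libraries. Of 100 random lists of 16 genes passed through the same steps, 4 fell outside it. The 3 contrasts of lists within libraries used an exact two-sided sign-flip test over 3 differences.

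Isoform ratios are log2 of summed TPM + 0.1 of isoforms annotated with a retained intron over that of protein-coding isoforms, tested against 0 with limma 3.58.1 (moderated, Benjamini-Hochberg) in 5598 genes with a mean count of at least 50. On simulated data for this comparison, 60% of genes shifted by 2 and 97% of those shifted by 4 on the log2 scale were recovered. There were 4 false calls among the unshifted of 5598 genes. The simulated ratios were normally distributed with the fitted spread. They held no zeros and no error in assigning reads, so false calls from these are not covered. Variation between libraries was tested on rounded expected counts of 14200 genes with a mean of at least 10 by a chi-square test with trimmed-mean (TMM) factors from edgeR 4.0.16, which also gave the coefficient of variation. For this test, simulation of Poisson counts recovered 60% of genes changed 1.5-fold and 99% of those changed 3-fold in 1 library, with 3 false calls among the unchanged of 14200. The departure of a list in 1 library is the median over members of log2(TMM-scaled CPM + 0.1) minus the mean of the other libraries, set among 10000 random lists matched on mean expression in 10 bins, for lists with at least 5 members of mean count 10 or more. It was added after the data were seen.

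Alternatives were thresholds of 0.1 and 5 TPM, shares of counts, length-matched or detected-only random lists, levels not divided by length, pseudocount 1, list means, other count filters, size factors from DESeq2 1.42.0 or library totals, the other quantifier, and leaving out each library in turn. Scripts ran in R 4.3.3 and Python with pandas, numpy and scipy. An untreated sample, other fractions and other times were not analysed here.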

Results

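Total RNA bound to chromatin was sequenced after ribosomal RNA depletion from bone marrow-derived macrophages of C57BL/6J mice, primary phagocytes grown out from marrow progenitors. The cells had been exposed for 120 min to 100 ng/ml of lipid A, the membrane anchor of bacterial lipopolysaccharide and the ligand of the receptor TLR4. The series holds 1 group of 3 libraries, labelled biological replicates 1, 2 and 3, so the values below describe stimulated cells and no untreated level was analysed here. The 3 libraries carry the same donor label, and nothing in the labels says whether they came from separate cultures, so every spread and p given here covers the difference between these libraries, which may be technical. Starting RNA differed between them, with 1 µg for replicate 1, 250 ng for replicate 2 and 500 ng for replicate 3, and cannot be separated from replicate. Expected counts per library summed to 19919358, 20430415 and 22023921 in replicates 1, 2 and 3. A count of 0 in a library allows a level of up to 0.1519, 0.1473 and 0.1365 CPM (counts scaled to the library's gene total) in replicates 1, 2 and 3, for counting error only. Levels are given as TPM (length-scaled transcript abundance) as deposited, as mean ± SD over the 3 libraries (n = 3), with positions on the mouse build mm10.

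By TPM, the chromatin fraction was led by small structural RNAs and the ribosomal DNA locus, while small noncoding RNAs held 2.088% ± 0.6054 of expected counts. Among genes of at least 200 nt, the highest mean TPM belonged to Rmrp, the RNA of the ribonuclease MRP complex (chromosome 4, 43492788 to 43493058). It had 104248 ± 17188 TPM but 0.73% ± 0.36 of expected counts. An overlapping lincRNA entry of the same symbol on the same strand stood at 29812 ± 11853 TPM, and how reads were split between both is uncertain. Gm26917 (chromosome 17, 39843013 to 39846341) had 75492 ± 6753 TPM and took 25% ± 4.4 of all expected counts. It lies beside Gm42418 (chromosome 17, 39846958 to 39848788, 17464 ± 2439 TPM) and the opposite-strand rRNA entry CT010467.1 (23645 ± 8721 TPM), which overlap each other. The signal recognition particle RNAs Rn7s1 and Rn7s2 shared identical values of 31750 ± 22776 TPM, as entries of identical sequence would, and the transcription elongation regulator Rn7sk stood at 18861 ± 11718 TPM. Among the guide RNAs of nucleolus and Cajal body, Scarna10 had 9692 ± 1049 TPM, Snora73b 6769 ± 1746, Snora73a 6608 ± 1475, Gm22009 6032 ± 1007 and Snord17 4876 ± 1116, and Rpph1, the RNA of ribonuclease P, had 3940 ± 3562 TPM. Replicate 2 raised several of these means, which without it were 18889 TPM for Rn7s1 and Rn7s2, 12333 for Rn7sk and 1897 for Rpph1. Small nucleolar RNAs of any length held 32.05% ± 7.463 of summed TPM but 5.895% ± 2.579 with the other quantifier and 0.3008% ± 0.138 of expected counts, so their TPM is uncertain, and those shorter than 200 nt were not ranked. With the other quantifier Gm26917 (83455 TPM) and CT010467.1 (63183 TPM) stood above Rmrp (45137 TPM), and Rn7s1, Rn7s2, Rn7sk, Scarna10, Snora73b, Snora73a, Gm22009, Snord17 and Rpph1 were lower, at 14015, 14015, 8719, 5161, 2245, 2133, 3144, 2001 and 1703 TPM.

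Nuclear long noncoding RNAs were abundant. Malat1, a nuclear speckle RNA (chromosome 19, 5795690 to 5802672), reached 10416 ± 3070 TPM, and Xist, the RNA that coats the inactive X chromosome, 982 ± 229 TPM. All 9 listed nuclear-retained RNAs had a mean above 1 TPM, down to Pvt1 at 2.34 ± 0.39 TPM (5.073 with the other quantifier), and the list's median of 109.5 ± 7.70 TPM lay at percentile 100.0 among 10000 random lists of the same size drawn from all annotated genes. Such random lists had a median of -3.32 on the log2(TPM + 0.1) scale, the value of undetected genes. Lists of detected RNAs readily reach that percentile, and the mitochondrially encoded list below was placed among the same genes. Protein-coding genes held 22.0% ± 3.51 of summed TPM, small noncoding RNAs 59.6% ± 4.35 and long noncoding RNAs 15.2% ± 1.31. The long noncoding class includes Gm26917, Gm42418 and the lincRNA entry of Rmrp, at 75492, 17464 and 29812 TPM. These set most of its share, while Malat1 had 10416 TPM. By expected counts, which are not divided by length, the protein-coding share was 57.6% ± 2.82, and it was 28.6% ± 6.57 of TPM with the other quantifier deposited for each library. Levels of mRNAs below are therefore small as TPM, since short RNAs set much of the total.

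In every library, 10205 annotated genes had at least 1 TPM. Of these, 8233 were protein-coding, out of 22028 annotated, 1332 were long noncoding and 150 small noncoding. The count was 15563 at a threshold of 0.1 TPM, 5444 at 5 TPM and 16095 with the other quantifier at 1 TPM.

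Genes of the type I interferon response had the highest level of the 25 lists averaged over libraries, while in replicate 2 mitochondrially encoded genes were above them. All 23 members had a mean above 1 TPM and their median was 197 ± 51.2 TPM. Mx1, an antiviral dynamin-like GTPase (chromosome 16, 97447035 to 97462907), was the highest protein-coding gene of the whole table at 2249 ± 577 TPM, with 1841, 1996 and 2908 TPM in replicates 1, 2 and 3. Rsad2, which encodes the antiviral enzyme viperin (chromosome 12, 26442746 to 26456452), had 1124 ± 348 TPM. Mx2, annotated as a polymorphic pseudogene (chromosome 16, 97535308 to 97560900), had 1030 ± 220.0 TPM. Mx1 and Rsad2 were at 3575 and 1739 TPM with the other quantifier. Lowest was Ifnb1, the interferon that TLR4 signalling through TRIF induces (chromosome 4, 88522025 to 88522774), at 9.01 ± 2.19 TPM. The interferon list's percentile among random lists of protein-coding genes was 100.0, and it stood above the cytokine list by 3.32 ± 0.24 on the log2(TPM + 0.1) scale, or 9.97-fold, in 3 of 3 libraries. An exact two-sided sign-flip test gave p = 0.25, the smallest that 3 libraries allow, and 0.75 after Benjamini-Hochberg adjustment over 3 such contrasts, so this test cannot reach 0.05. The difference was 4.20 without division by length and 4.14 with list means.

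**Figure D1:**
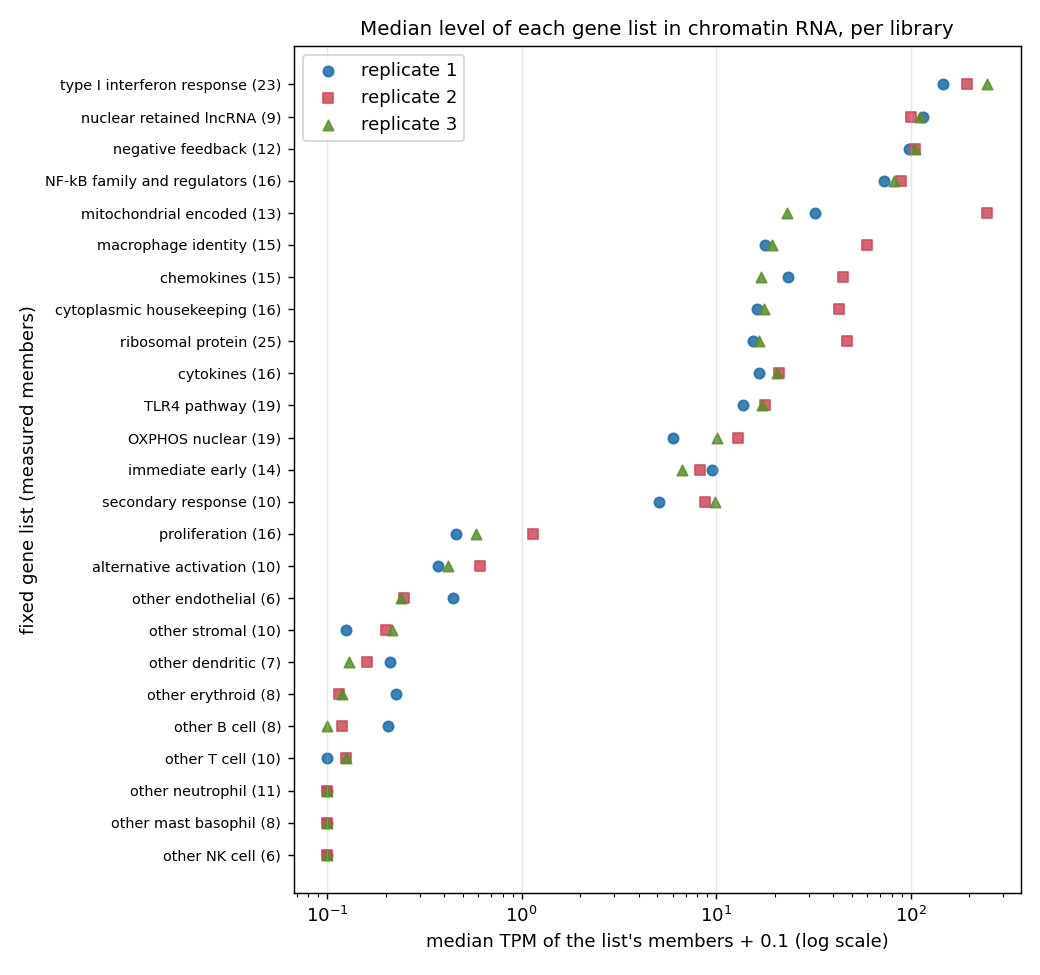
Median TPM plus 0.1 (horizontal log axis) of the measured members of each of the 25 fixed gene lists (vertical axis, member number in brackets), 1 point per library. The interferon list lies at 146, 196 and 249 TPM in replicates 1, 2 and 3, highest in replicates 1 and 3 and below mitochondrially encoded genes in replicate 2, while markers of other cell types lie near 0 and the mitochondrial, ribosomal protein and housekeeping lists are set apart in replicate 2.

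Regulators of NF-kB, the transcription factor family that TLR4 activates, came next among the protein-coding response lists together with negative feedback genes. Tnip3, an inhibitor of NF-kB signalling (chromosome 6, 65525313 to 65634040), had 528 ± 97.53 TPM, and the ubiquitin-editing enzyme gene Tnfaip3 (chromosome 10, 19000910 to 19015657) had 461 ± 100.1 TPM. Nfkbia, which encodes the inhibitor IκBα (chromosome 12, 55489410 to 55492647), had 328 ± 30.9 TPM, and the lowest of the 16 NF-kB genes, the deubiquitinase gene Cyld, had 14.7 ± 2.46 TPM. The NF-kB list's median was 81.5 ± 8.05 TPM. The 12 negative feedback genes had a median of 103 ± 4.19 TPM, with the checkpoint ligand gene Cd274 at 309 ± 132 TPM beside Tnfaip3 and Nfkbia, and Irak3, which encodes a kinase-like inhibitor of the receptor complex, lowest at 6.04 ± 1.26 TPM. Members of the TLR4 pathway itself were lower, with a median of 16.2 ± 2.21 TPM over 19 genes. Within it Ikbke, an interferon-inducing kinase (chromosome 1, 131254343 to 131279606), had 767 ± 65.5 TPM, Ikbkb 105 ± 24.7, Tbk1 94.3 ± 11.4 (145.3 with the other quantifier), and Ticam1, which encodes the adaptor TRIF, 4.54 ± 1.10. Each of these 3 lists was at percentile 100.0 among random protein-coding lists.

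Cytokine and chemokine genes were present over a wide range. Tnf (chromosome 17, 35199381 to 35202007) had 206 ± 44.5 TPM, Il1b 129 ± 97.3 (72.74 without replicate 2), Csf1, the macrophage growth factor gene, 95.7 ± 0.907, and Csf3, the granulocyte growth factor gene, 0.11 ± 0.105. The cytokine median was 19.4 ± 2.43 TPM, and 14 of 16 members had a mean of at least 1 TPM. Among the chemokines, ligands that attract leukocytes, Cxcl10 (chromosome 5, 92346638 to 92348889) had 606 ± 155 TPM, Ccl5 594 ± 231 and Ccl4 349.7 ± 137, while Cxcl5 had 0.03 ± 0.052 TPM (1.547 with the other quantifier). The chemokine median was 28.4 ± 14.7 TPM, with 12 of 15 members at 1 TPM or more, and both lists lay at percentile 100.0. Reads of Ccl3, Ccl4 and other clustered chemokine genes can be shared between paralogs.

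Immediate early genes, the class transcribed first after a stimulus, were modest at 120 min. The phosphatase genes Dusp2 (chromosome 2, 127336159 to 127338376) and Dusp1 (chromosome 17, 26505590 to 26562128) had 177 ± 34.7 TPM and 83.9 ± 8.64 TPM, and Zfp36, which encodes an mRNA-destabilising protein, had 58.7 ± 9.70 TPM. Egr3, a zinc finger factor, had 0.737 ± 0.53 TPM. The 14 members had a median of 8.05 ± 1.41 TPM at percentile 99.6. Secondary response genes, which need protein synthesis or chromatin remodelling, were at a median of 7.81 ± 2.52 TPM and percentile 98.88. The nitric oxide synthase gene Nos2 (chromosome 11, 78920787 to 78960254) had 29.7 ± 8.33 TPM (57.04 with the other quantifier), Il12b 27.6 ± 10.9, Ebi3 21.2 ± 2.5 and Csf3 again the least. Secondary minus immediate early genes was -0.09 ± 0.82 on the log2 scale, with -0.95, 0.01 and 0.67 in replicates 1, 2 and 3, and did not stand apart from the spread (exact sign-flip p = 1.0, adjusted 1.0). Without replicate 1 the difference was 0.34, and it was 0.84 with the other quantifier. Against detected genes only, the immediate early list stood at percentile 87.51 and the secondary list at 67.58.

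Macrophage genes were present, with a median of 32.3 ± 23.9 TPM over 15 members at percentile 100.0, made up of 17.9, 59.9 and 19.2 TPM in replicates 1, 2 and 3. Lyz2, the macrophage lysozyme gene (chromosome 10, 117277331 to 117282321), had 334 ± 468 TPM, made up of 88.9, 873 and 39.0 TPM in replicates 1, 2 and 3, so replicate 2 set its mean, which was 63.94 TPM without it and 198.5 TPM with the other quantifier. The transcription factor gene Irf8 had 249.8 ± 69.6 TPM (431.3 with the other quantifier), the scavenger receptor gene Msr1 210.2 ± 36.1 and Cebpa 0.86 ± 0.46. Genes of alternative activation, the state driven by interleukin 4, had a median of 0.368 ± 0.13 TPM and lay within the central 95% of random lists at percentile 55.09. Only 3 of its 10 members reached a mean of 1 TPM, namely the receptor genes Il4ra (198 ± 43.5 TPM), Mrc1 (117 ± 10.5 TPM) and Clec10a (1.13 ± 0.981 TPM, but 0.585 without replicate 2). Against detected genes only, its percentile was 99.72 on these 3 members. Mgl2 had a count of 0 in every library. Proliferation genes had a median of 0.628 ± 0.366 TPM at percentile 67.74, and at 0.01 against detected genes only, on 6 members. Against that median Mki67, a proliferation antigen gene (chromosome 7, 135689784 to 135716361), stood at 31.4 ± 0.691 TPM and Pcna, a DNA replication clamp gene, at 22.7 ± 7.61 TPM, while Mcm5 had 1.40 ± 1.01 TPM (0.9 without replicate 3) and Plk1 0.177 ± 0.0586 TPM.

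Medians of the 9 lists of markers of other cell types were at most 0.212 TPM. For T cells, Cd28 had 6.67 ± 6.08 TPM (3.175 without replicate 2), Il7r 5.71 ± 3.29, Lck 3.66 ± 1.46 and Trbc2, the receptor beta constant gene, 0 in every library, with a list median of 0.0167 ± 0.0144 TPM. Of the B cell genes Ighm had 0.217 ± 0.175 TPM, Ebf1 0.143 ± 0.248 and Blk 0. In the NK cell list Klrk1 had 1.60 ± 0.554 TPM, Ncr1 0.0133 ± 0.0231, Eomes 0.00333 ± 0.00577 and Gzma 0. Neutrophil genes were led by S100a9 at 0.447 ± 0.461 TPM, S100a8 at 0.403 ± 0.55 TPM and Mmp8 at 0.26 ± 0.4 TPM, which without replicate 2 were 0.21, 0.09 and 0.03 TPM, with Cxcr2 at 0. The dendritic cell factor gene Zbtb46 had 0.893 ± 0.42 TPM, Clec9a 0.15 ± 0.0755, Xcr1 0.0933 ± 0.0306 and Cd209a 0. Mast cell and basophil genes comprised Kit at 1.17 ± 0.306 TPM, Gata2 at 0.04 ± 0.04 TPM, Ms4a2 at 0.04 ± 0.0529 TPM and Mcpt8 at 0. Erythroid genes included Alas2 at 1.85 ± 1.26 TPM, Epor at 0.203 ± 0.123 TPM and Hba-a1 at 0.17 ± 0.181 TPM. Among stromal genes Col1a1 had 0.4 ± 0.113 TPM, Col1a2 0.19 ± 0.131, Pdgfrb 0.177 ± 0.0651 and Lum 0.0133 ± 0.0115. The endothelial list held 2 genes above 1 TPM, Vwf (chromosome 6, 125546774 to 125686679) at 20.3 ± 3.89 TPM and Kdr at 4.54 ± 1.16 TPM, beside Pecam1 at 0.337 ± 0.212 TPM and Emcn at 0. Other means below 1 TPM can also come from 1 library, as for Ebf1, which was 0 without replicate 2. Levels of several markers were higher with the other quantifier, at 6.747 TPM for Pecam1, 4.652 for Alas2, 3.914 for Cxcr2, 7.073 for Lck, 2.138 for Ebf1, 1.576 for Zbtb46, 0.9084 for Col1a1, 0.8174 for Xcr1 and 0.5438 for Eomes, so a low value or 0 for a single one of these genes depends on the quantifier. List percentiles ran from 4.14 for mast cells and basophils, 4.93 for NK cells, 6.02 for neutrophils, 16.61 for T cells and 22.34 for B cells to 25.43, 30.26, 35.68 and 39.59 for the erythroid, stromal, dendritic and endothelial lists, all within the central 95% of random lists. The mast cell and basophil, NK cell and neutrophil lists had a median of 0 in every library, the lowest possible. Ties with random lists set their percentiles, so this placement could not call them below. With the other quantifier the mast cell and basophil list fell outside the central range.

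Genes whose mature mRNAs are abundant in cytoplasm and mitochondria were set apart in replicate 2. Mitochondrially encoded genes had medians of 32.2, 246 and 23.0 TPM in replicates 1, 2 and 3. The cytochrome oxidase subunit gene mt-Co1 (chromosome M, 5328 to 6872) had 83.5, 1246 and 149.8 TPM, mt-Atp8 46.4, 1483 and 189.5 TPM and mt-Nd6 60.2, 388 and 51.8 TPM, whereas mt-Co2, whose reads can also be placed on a nuclear pseudogene, had 31.8, 15.7 and 0 TPM. Ribosomal protein genes had medians of 15.4, 47.0 and 16.6 TPM, and all 25 were highest in replicate 2 after trimmed-mean scaling of counts. Rplp1 had 15.6, 154 and 10.6 TPM, Rps2 24.1, 69.9 and 27.3 TPM, Rps14 19.1, 77.2 and 25.02 TPM and Rps3, the lowest by mean, 8.64, 20.8 and 9.47 TPM. Cytoplasmic housekeeping genes had medians of 16.2, 42.8 and 17.6 TPM, with the actin gene Actb at 342, 792 and 339 TPM, the elongation factor gene Eef1a1 at 123, 430.2 and 130.3 TPM, B2m at 69.5, 395 and 80.6 TPM and Hprt at 3.62, 12.3 and 3.32 TPM. Nuclear genes of oxidative phosphorylation had a median of 9.63 ± 3.54 TPM, with Atp5b at 57.3 ± 21.7 TPM, Cox4i1 at 25.04 ± 19.3 TPM (13.93 without replicate 2), Sdha at 24.1 ± 6.21 TPM and Ndufb3 at 1.81 ± 1.21 TPM (1.115 without replicate 2). Means over libraries with the other quantifier were 132.1 TPM for mt-Atp8, 308.0 for mt-Co1, 97.75 for mt-Nd6, 51.4 for mt-Co2, 34.22 for Rplp1, 48.87 for Cox4i1 and 43.53 for Sdha, against 573.0, 493.1, 166.6, 15.82, 60.03, 25.04 and 24.15 TPM from the main tables. These 4 lists lay at percentiles 100.0, 100.0, 100.0 and 99.97, and the last stood at 71.05 among detected genes. Ribosomal protein minus cytokine genes was 0.25 ± 0.80 on the log2 scale, with -0.09, 1.16 and -0.31 per library (exact sign-flip p = 1.0, adjusted 1.0), and without replicate 2 it was -0.20.

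Within genes, isoforms annotated with a retained intron were compared with protein-coding isoforms to ask which spliced form chromatin RNA was assigned to. Retained-intron TPM exceeded coding TPM in 1084 of 5598 tested genes and lay below it in 1668 (limma, adjusted p below 0.05). The largest excess was at Lilrb4a, an inhibitory receptor gene (chromosome 10, 51490956 to 51496611), with a log2 ratio of 11.84 ± 0.69 (SE, n = 3, limma adjusted p = 0.000487). Uba7, which encodes the enzyme that activates the ubiquitin-like ISG15 (chromosome 9, 107975505 to 107984060), had 8.17 ± 0.39, and the fatty acid transporter gene Slc27a1 (chromosome 8, 71568882 to 71587302) had 7.82 ± 0.26. Psd, Rsrp1, Dgkq, Spaca6 and Plpp5 had log2 ratios of 7.71, 6.37, 6.30, 6.00 and 5.82. At the other end were Ccdc88b (chromosome 19, 6844623 to 6858211) with -8.75 ± 0.29, the phosphodiesterase gene Pde4b (chromosome 4, 102087543 to 102607259) with -8.26 ± 0.27 and Hivep2 with -8.08 ± 0.27. Igsf8, Plxna1, Wdfy3, Ccdc167 and the apolipoprotein gene Apoe had -7.83, -7.72, -7.58, -7.22 and -7.16. Sizes depended on the quantifier, and with the other one the ratio was 9.95 for Lilrb4a, 9.87 for Uba7, 3.63 for Slc27a1, 3.80 for Spaca6 and 2.99 for Plpp5, and -5.44 for Ccdc88b, -4.62 for Pde4b, -4.50 for Ccdc167, -3.82 for Hivep2 and -2.82 for Plxna1. Where one class was at 0 the ratio is set by the added 0.1 TPM and is no measure of size. Mean retained-intron TPM was 0.0 for Ccdc88b, Pde4b, Hivep2, Igsf8 and Ccdc167. Mean coding TPM was 0.0 for Slc27a1 and Plpp5 and 0.01 for Psd. Lilrb4a had ratios of 10.78, 10.73 and 14.02 in replicates 1, 2 and 3, at a mean coding TPM of 0.31. Plxna1 had -6.68, -6.74 and -9.75, at a mean retained-intron TPM of 0.46. Replicate 3 thus set part of the mean for Lilrb4a and Plxna1, whose lower class lay near the added 0.1 TPM.

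**Figure D2:**
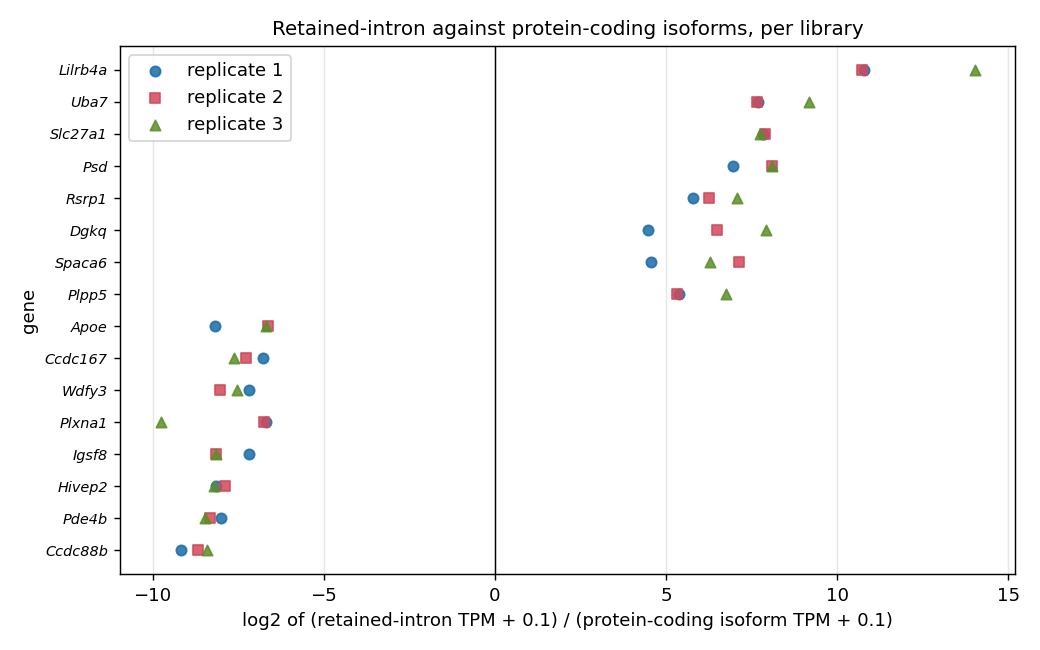
Log2 ratio of retained-intron to protein-coding isoform TPM, each plus 0.1 (horizontal axis), for 16 genes (vertical axis), 1 point per library. Ratios of the 8 upper genes lie above 0 in all 3 libraries, led by Lilrb4a with a mean of 11.84, and those of the 8 lower genes lie below 0.

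Response genes fell on both sides. In the interferon list 3 of 13 tested genes had more retained-intron TPM, Oasl2 (3.11 ± 0.28), the interferon regulatory factor gene Irf7 (2.61 ± 0.26) and Mx1 (1.63 ± 0.26), and 2 had less, among them Irf1 (-1.18 ± 0.27). Adjusted over the list alone the counts were 3 and 2 as well. Of 12 NF-kB genes 2 were higher, Tnip3 (3.24 ± 0.28) and Nfkb1 (1.09 ± 0.33), and 5 lower, with Nfkb2 at -3.47 ± 0.26 and Nfkbia at -3.19 ± 0.26, and the counts adjusted over the list alone were again 2 and 5. With the other quantifier Nfkbia was at -0.76, Nfkb2 at -2.47, Tnip3 at 2.34, Oasl2 at 2.52 and Irf1 at -2.03. For the 14 TLR4 pathway genes the counts were 2 and 5, for 6 negative feedback genes 1 and 3, for 7 chemokine genes 1 and 0 and for 5 macrophage genes 0 and 3, with the same counts adjusted over the list alone. Ribosomal protein genes had 3 higher and 4 lower of 20, or 2 and 4 adjusted over the list alone, and oxidative phosphorylation genes 1 and 3 of 11, or 1 and 2. Housekeeping genes had 1 and 5 of 14, and 1 and 5 adjusted over the list alone. Over all tested genes 19.36% were higher and 29.8% lower. Among random lists, percentiles of the list medians ran from 6.55 for housekeeping to 94.87 for interferon genes, all within the central 95%. No list therefore stood apart in its median ratio. With the other quantifier 1874 genes were higher and 1701 lower, and with reads not divided by isoform length 743 and 3201. Without replicate 1, 630 were higher and 936 lower, and without replicate 3 the counts were 828 and 1824.

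The spread between libraries was compared with counting noise, which separate libraries at this depth exceed in any case, so the count describes their spread and decides nothing about its source. Of 14200 genes with a mean count of at least 10, 9769 varied more than Poisson counting allows (chi-square test, Benjamini-Hochberg adjusted p below 0.05), and the common biological coefficient of variation from edgeR was 0.333. Among genes with a mean count of at least 100, the widest spread per mean count belonged to mt-Atp6, an ATP synthase subunit gene (chromosome M, 7927 to 8607), with counts of 0, 684 and 0 in replicates 1, 2 and 3. Its nuclear pseudogene Gm10925 on chromosome 1 shares 629 of 632 windows of 50 nt with it, and their summed counts were 390, 5411 and 418. Gm28661 (chromosome 1, 24614885 to 24615565), with counts of 126, 8368 and 684, shares 632 of 635 windows of mt-Co2, and that pair summed to 479, 8509 and 684. The glutamate transporter gene Slc1a2 (chromosome 2, 102658659 to 102790784) had 397, 5 and 16 counts, 9130230L23Rik 509, 11 and 28, and Ebpl 675, 25 and 28. Gm24497, an snRNA entry of 191 nt (chromosome 1, 72244213 to 72244403), had 1.3, 3.2 and 1432 counts. Leaving out 1 library gave 6687 to 7755 varying genes.

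Gene lists departed together. Relative to the mean of the other libraries on the log2 scale of scaled counts, replicate 2 was higher by a median of 3.42 for 13 mitochondrially encoded genes, 1.53 for 25 ribosomal protein genes, 1.43 for 16 housekeeping genes and 0.80 for 15 macrophage genes, each at percentile 100.0 among lists matched on expression. For macrophage genes 8 of 15 were highest in replicate 2, and with the other quantifier 6 of 15, with a median of 0.34 against 0.37 in replicate 1. Among matched lists these medians of 0.34 and 0.37 lay at percentiles 99.98 and 84.79. Immediate early genes were highest in replicate 1 for 11 of 14 members, by a median of 0.68, or 1.08 with the other quantifier, and all 14 lay below the mean of the other libraries in replicate 3, at a median of -0.91 and percentile 0.0. By TPM the list median was also lowest in replicate 3 (9.405, 8.155 and 6.585 TPM in replicates 1, 2 and 3). Its 3 highest members, Dusp2, Dusp1 and Zfp36, had their highest TPM there, with Dusp2 at 146.2, 169.6 and 214.6. Protein-coding genes held 17.97%, 23.72% and 24.33% of summed TPM in replicates 1, 2 and 3, so TPM is not directly comparable between libraries. By scaled CPM, Dusp1 (151.6, 114.2 and 113.6) and Zfp36 (145.8, 152.0 and 135.8) were lowest in replicate 3. Dusp2 (179.7, 160.5 and 166.9) was lowest in replicate 2. Other lists also lay below the mean of the other libraries in replicate 3 by scaled counts. Medians were -2.32 for mitochondrially encoded, -1.15 for macrophage, -1.09 for housekeeping, -1.01 for ribosomal protein and -0.68 for chemokine genes. That mean includes replicate 2, where these lists were raised. Against replicate 1 alone, replicate 3 medians were -0.33 for ribosomal protein, -0.83 for immediate early and -0.90 for mitochondrially encoded genes. Interferon genes were at 0.21 in replicate 3, percentile 99.99, with 13 of 23 members highest there. With the other quantifier the median was 0.03, again at percentile 99.99, although 17 of 23 were highest in replicate 1. All protein-coding genes with that quantifier had medians of 0.11 in replicate 1 and -0.18 in replicate 3. In replicate 2 cytokine and chemokine genes were at 0.43 and 0.64, percentiles 99.78 and 100.0, the latter at 0.37 with the other quantifier, and the 9 nuclear-retained RNAs at 0.00, percentile 77.44.

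**Figure D3:**
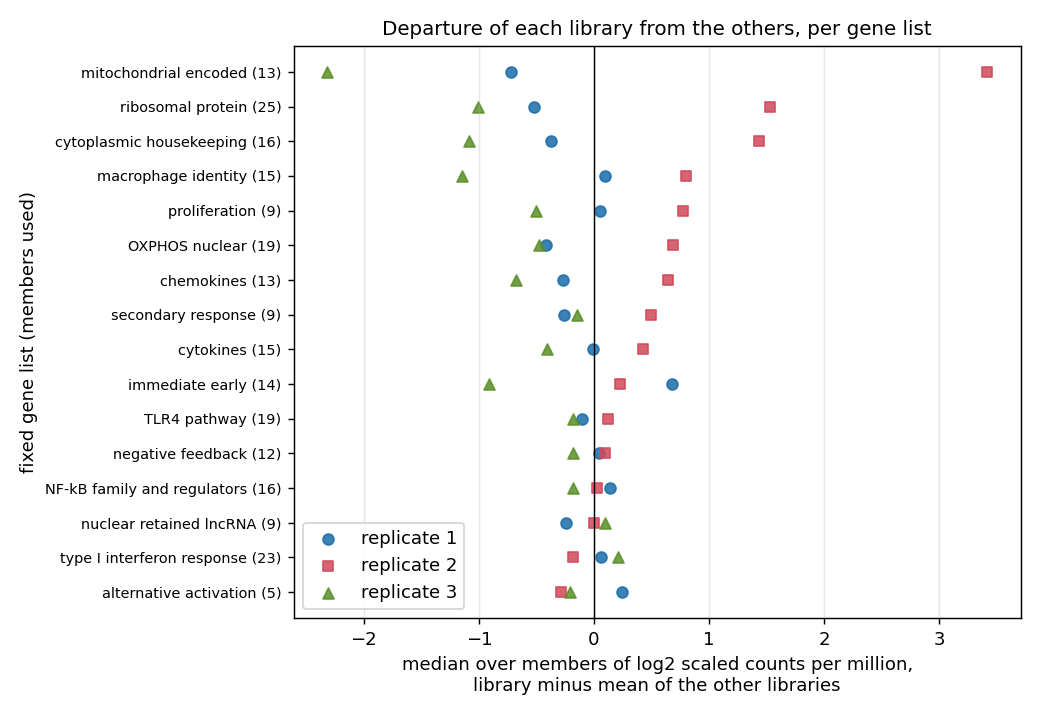
Median over list members of the log2 scaled CPM in 1 library minus the mean of the other libraries (horizontal axis), per gene list (vertical axis, members used in brackets). Replicate 2 stands at 3.42 for mitochondrially encoded genes and 1.53 for ribosomal protein genes, and immediate early genes lie at 0.68 in replicate 1 and -0.91 in replicate 3.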

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

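Reads of the bacteriophage phiX174 genome, a sequencing control outside the genes compared above, were present in all 3 libraries, far above the floor of 3 counts. They made up 0.845% of expected counts in replicate 1 (exact 95% interval 0.841 to 0.849), 0.282% in replicate 2 (0.279 to 0.284) and 0.179% in replicate 3 (0.177 to 0.181). RNA spike-in entries had 1, 0 and 0 counts.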

How the results depend on the processing

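Alternatives were fixed before the data were examined, except those for departures of single libraries and for single genes and the direction of called isoform ratios with the other quantifier. The split of isoform calls by direction was added later, under the fixed alternatives. All 25 lists stayed within or outside the central 95% of random lists, as before, under length-matched random lists, levels not divided by length and each left-out library. Against detected genes only, 3 lists fell within the central range, immediate early to 87.51, secondary to 67.58 and oxidative phosphorylation to 71.05, while alternative activation rose to 99.72 on 3 members and proliferation went to 0.01 on 6. No value came from that alternative for the B cell, neutrophil, dendritic and stromal lists, which have no member at 1 TPM. With the other quantifier immediate early stood at 96.22 and mast cells and basophils at 2.11, and the other 23 lists stayed within or outside it as before, although T cells went from 16.61 to 58.98.

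Detected genes numbered 15563 and 5444 at 0.1 and 5 TPM and 16095 with the other quantifier, and the protein-coding share was 57.58% by counts and 28.55% with the other quantifier. Interferon minus cytokine genes kept its sign under every alternative run, at 4.20 without division by length and 4.14 with list means. Secondary minus immediate early genes went to 0.0 without division by length and changed sign to 0.84 with the other quantifier, and ran from -0.47 to 0.34 with 1 library left out. Ribosomal protein minus cytokine genes changed sign to -0.04 for members at 1 TPM or more, -0.53 without division by length and -0.11 with the other quantifier, and ran from -0.20 to 0.54 with 1 library left out. Neither contrast had passed a threshold, and the cause was not tested.

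Isoform calls came to 1526 in both directions together with no count filter (627 higher, 899 lower) and to 1539 at a mean count of 500 (605 and 934, with fewer genes tested). The other quantifier gave 1874 higher, and reads not divided by length 3201 lower. With 1 library left out, totals ran from 1566 to 2652, higher calls from 630 to 951 and lower calls from 936 to 1824. The cause of these shifts, beyond fewer genes or libraries, was not tested. Of the main calls, 1048 higher and 1483 lower genes kept their direction with the other quantifier. Of 10 departures of single libraries, 9 kept their direction under DESeq2 size factors and the other quantifier. With the other quantifier, interferon genes in replicate 3 fell to 0.03 and macrophage genes in replicate 2 to 0.34, at percentiles 99.99 and 99.98. Nuclear-retained RNAs in replicate 2 went from 0.00 to -0.07 under each. Varying genes stayed within 1.5 times of 9769 under each alternative. Of the TPM of 116 single genes, 107 moved by more than 1 SD when rescaled to nuclear protein-coding genes (Mx1 to 10291) and 54 with the other quantifier. Leaving out 1 of 3 libraries cannot move a mean by 1 SD and says nothing on stability, and Lyz2 went from 333.7 to 63.94 TPM without replicate 2.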

Other observations

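Of the 18 protein-coding genes with the highest mean TPM, 13 stood outside the fixed lists and are named here after their values were seen. Tnfaip2, a TNF-induced gene, had 1345 ± 172 TPM, the inhibitory receptor genes Lilrb4a and Lilr4b 1224 ± 417 and 1063 ± 174, the E3 ligase gene Rnf213 1204 ± 183 and the ADP-ribosyltransferase gene Parp14 1033 ± 329. Lilrb4a and Lilr4b are close paralogs and can share reads. The NF-kB pathway protease gene Malt1 had 720.2 ± 188 TPM, and the restriction factor gene Samhd1 had 621 ± 294 TPM, with 383, 529 and 949 TPM in replicates 1, 2 and 3. The others were Gm21887 at 933.1 ± 131.5 TPM, Tcirg1 at 895.3 ± 98.67, Zc3h7a at 709.0 ± 251.2, Zeb2 at 696.8 ± 218.0, Ahnak at 654.3 ± 69.88 and Fchsd2 at 629.3 ± 149.2.

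Long noncoding genes outside the lists included Lncpint at 284 ± 104 TPM and Mir155hg, the host gene of microRNA 155, which had 50.6, 157 and 266 TPM in replicates 1, 2 and 3. Genes of the annotation class TEC, models awaiting experimental evidence, had a median departure of -0.50, -0.03 and 0.53 in replicates 1, 2 and 3 over 1048 genes, and sense intronic genes -0.49, -0.09 and 0.68 over 141. With the other quantifier these were smaller, at -0.19, -0.05 and 0.23 for TEC and -0.25, -0.10 and 0.31 for sense intronic genes. Snord22, a short snoRNA, had 67934, 0 and 0 TPM (3238 on average with the other quantifier) but 2197, 1068 and 1741 counts, so its TPM does not follow its counts.

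Of the tests in the next paragraphs, that of intron ratios among genes higher in replicate 2 and that of gene span were set before their results were seen, and the others after. No biological explanation was tested, since the labels name no difference between the libraries beyond starting RNA.

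Lists of cytoplasmic and mitochondrial mRNAs were higher in replicate 2, while of 11013 protein-coding genes with a mean count of at least 10, 299, 959 and 178 lay over 2-fold above the mean of the other libraries in replicates 1, 2 and 3 and 481, 118 and 851 over 2-fold below it. Scaling or composition alone is argued against, because the ribosomal protein minus interferon difference within replicate 2 lay 1.51 above the mean of the others (-2.06 against -3.24 and -3.90), and no scaling factor moves it. Cytoplasmic RNA left in the fraction is a candidate explanation: among 304 genes over 2-fold higher in replicate 2, the retained-intron to coding ratio was lower there by a median of -1.87 on the log2 scale (quartiles -2.59 and -1.21), against -0.14 in 3249 genes close to the other libraries. Coding isoforms count toward the totals by which the 304 genes were picked, so the picking itself can lower their ratio in replicate 2. The comparison genes were not picked that way, and genes higher in replicates 1 or 3 were not put through this step. The size of the contrast is therefore no measure of cytoplasmic RNA. The starting amount, lowest in replicate 2, is confounded with cytoplasmic RNA left in the fraction and stays open. A direct measure of the cytoplasmic fraction was not analysed here.

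Retained-intron isoforms above coding isoforms may owe part of their excess to the length by which reads are divided, since 74.7% of the 1084 genes kept more reads on retained-intron isoforms when reads were not divided by length, which does not decide the matter. Assignment by 1 quantifier is argued against as the whole cause, since 96.7% kept the direction with the other quantifier. Both quantifiers share out the same reads among annotated isoforms, so an error common to them is not covered. Unspliced precursor RNA counted on isoforms with a retained intron stays open, as coverage along introns was not analysed here.

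By scaled counts, immediate early genes lay below the mean of the other libraries in replicate 3 for 14 of 14 members. Macrophage, housekeeping and ribosomal protein genes were also below it, at medians of -1.15, -1.09 and -1.01. That mean includes replicate 2, where these other lists were raised, so their medians partly reflect its rise. Short gene bodies of immediate early genes do not account for their position, as their median of -0.91 lay at percentile 0.07 of random lists matched on expression and genomic span. Less cytoplasmic RNA in replicate 3 than in replicate 1 might contribute and cannot be told apart: the ribosomal protein median of replicate 3 over replicate 1 lay only 0.50 above the immediate early median (-0.33 against -0.83), and mitochondrially encoded genes were at -0.90. That -0.90 is affected by reads placed on nuclear copies. From replicate 1 to 3, mt-Co2 and mt-Co3 fell from 353 and 514 counts to 0 and 2. Summed with their copies, mt-Co2 and mt-Co3 rose from 479 and 551 to 684 and 916, and the mt-Atp6 pair from 390 to 418. The mt-Nd3 and mt-Nd4l pairs fell from 77 and 119 to 62 and 100. These sums are not scaled for library size. Replicate 3 had the larger gene total and TMM factor (1.0964 against 0.9097 in replicate 1), so scaling lowers it against replicate 1. A difference in the timing of the response was not tested.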
